A study of Homo sapiens with 6 samples.

How the data were processed

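Gene expression was measured in primary human keratinocytes with Affymetrix HG-U133 Plus 2.0 arrays, which hold 54675 probe sets. Each of the 6 arrays belongs to 1 of 3 groups with 2 arrays each, called control, KLF4 knockdown and ZNF750 knockdown, and the study's design text calls the 2 arrays of a group biological duplicates. Per the labels, cells were grown to full confluence, kept in medium with 1.2 mM calcium for 3 days to differentiate, and knocked down with siRNA. The labels of the control arrays give no treatment, and whether these cells received a non-targeting siRNA is not stated. Total RNA was labelled with biotin using a 3′ IVT kit.

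The deposited values are log2 expression values per probe set made by RMA, which corrects the background, normalizes the arrays to each other by quantiles and summarizes the probes of a set. The submitters' processing notes name RMA and R 2.11.1, and give no further settings. The values ran from 2.61 to 15.1, with a median of 5.21 over all probe sets and arrays. RMA gives no detection calls, so a low value cannot be told from background on a single array. Where the lower group mean of a gene lies under the median of all values, the size of its change is read as a lower bound. That reading holds for every such gene in the text, whether or not it is marked again there. No depth of counting exists for arrays, and their number limits the precision.

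Probe sets were named by the array's annotation, and 41091 of them carried 1 gene symbol. The 1801 probe sets with several genes, the 11721 with no gene and the 62 control probe sets were left out of the comparisons. Old symbols were brought up to date with a RefSeq gene table, and for 54 of the probe sets with 1 gene no match was found there and the old symbol was kept. Where a gene had several probe sets, which was so for 10523 genes, the probe set with the highest mean over all arrays stood for the gene, so that 19777 genes were tested. No filter on dim probe sets was applied and no column was left out. The control probe sets served only to describe the arrays. These were added poly-A control RNAs, which are mixed into the RNA before labelling, hybridisation controls, and probe sets at the 3′ and 5′ ends of ACTB and GAPDH.

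A linear model with a mean per group was fitted to all 6 arrays with limma 3.58.1 in R 4.3.3, with lmFit and eBayes. The fit had 3 residual and 4.11 prior degrees of freedom, and each group's spread was taken to be the same. The contrasts were KLF4 knockdown minus control, ZNF750 knockdown minus control, and ZNF750 knockdown minus KLF4 knockdown. Tests were two-sided and p-values were adjusted by the Benjamini-Hochberg method over the genes of a contrast, with a threshold of 0.05. A gene is said to have risen or fallen only where its adjusted p was under that threshold. Fold changes are on the log2 scale with the standard error of the contrast (SE), and levels are group means with the SD of 2 arrays. The model was tested on simulated data. These took the control mean and the spread of each gene from the arrays, and values were drawn independently for each gene with the same spread in every group. Of 100 genes given a change of 1 on the log2 scale it called 41, 28 and 37 in the 3 contrasts, and of 100 given a change of 2 it called 91, 83 and 81. Of the calls, 2.22%, 1.77% and 3.28% were false, which need not hold for genes that vary together. In further draws of this kind, with lists of genes picked at random, camera at its preset correlation called the 1 moved list in each contrast. It also called 1, 0 and 0 of the lists that had not been moved. Camera with an estimated correlation was not tested in this way.

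Lists of 22 gene groups, all fixed with their members before the data were examined, were tested with camera at its preset correlation between genes of 0.01, and p-values were adjusted over the lists of a contrast. There were 17 lists of pathways and functions. These were cornified envelope, epidermal lipid barrier, epidermal proteases and protease inhibitors, spinous layer differentiation, desmosomes, epidermal transcription factors, basal keratinocytes and hemidesmosomes, stress keratins and antimicrobial proteins, cell cycle, interferon response, inflammatory cytokines and NF-kB, cholesterol biosynthesis, mesenchymal and extracellular matrix genes, p53 targets, unfolded protein response, oxidative phosphorylation and ribosomal proteins. The other 5 held markers of melanocytes, fibroblasts, Langerhans cells and leukocytes, endothelial cells, and simple epithelium and Merkel cells. KLF4 and ZNF750 themselves were left out of the lists. For each list, the genes past the threshold were counted with p-values adjusted over all genes and adjusted over the list alone. As alternatives, camera was run with a correlation estimated for each list, and fry was run, which tests whether the genes of a list move on balance in one direction.

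Genes named in the text followed a rule written at the same early stage. It took KLF4 and ZNF750, the 8 largest rises and falls of each knockdown and the 5 largest each way between the knockdowns, among called genes whose arrays did not overlap between the groups and whose higher group mean was at or above the median of all values. From each list it took up to 4 called members with the largest change, or the 2 with the smallest p where fewer than 2 passed. Sex-linked marker genes and genes with uninformative names were not named, and not every gene the rule chose is given in the text. Genes outside this rule are marked in the text as chosen after their values were seen.

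Both knockdowns were set against the same 2 control arrays. Shared changes were therefore compared with the number that independent lists would give and with 100 draws of simulated unchanged groups set against the same controls. The alternatives were a mean-variance trend, a fit to the 4 arrays of a comparison alone, removal of dim probe sets, the mean of a gene's probe sets, every probe set on its own, a further quantile normalization, centred array medians, array weights, replicate number as a block, a 2-fold minimum, and the removal of each array in turn. Where an array was removed, its group kept 1 array, which was assumed to vary like the other groups. A crossed pairing of the replicate numbers was added after seeing the data, as was a list of amino acid response genes. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.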

Results

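The 6 arrays measured RNA levels in confluent primary human keratinocytes, the main cells of the epidermis, after 3 days in 1.2 mM calcium. Calcium is a signal that starts their terminal differentiation. The groups were control, KLF4 knockdown and ZNF750 knockdown, with 2 arrays each. KLF4 and ZNF750 are zinc finger transcription factors of the upper epidermis, and the series title states that ZNF750 drives terminal differentiation by inducing KLF4. The comparisons ask what each knockdown changed and how far the changes were shared. Across the genes tested, with 1 probe set each, the arrays of a group correlated at 0.989 to 0.993, and the highest correlation between arrays of different groups was 0.981. The first principal component held 64.3% of the variance. On it the control arrays lay at -69.7 and -54.0, the ZNF750 knockdown arrays at -9.33 and 21.8, and the KLF4 knockdown arrays at 62.3 and 49.0. The second component held 25.3% and set the ZNF750 knockdown arrays (-36.6 and -47.2) apart from the others. On it control lay at 27.6 and 4.11 and the KLF4 knockdown at 21.0 and 31.2.

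ZNF750 RNA (1 probe set, chromosome 17) was at 11.63 and 11.96 in the control arrays, 12.04 and 12.12 in the KLF4 knockdown and 10.07 and 9.76 in the ZNF750 knockdown. It fell by 1.88 in the ZNF750 knockdown (SE 0.18, adjusted p 0.00371), to 27.2% of control. In the KLF4 knockdown its difference from control was 0.29 (SE 0.18, adjusted p 0.311), which did not pass the test. KLF4 RNA (the brighter of its 2 probe sets, chromosome 9) was at 13.22 and 13.07 in the control arrays, 12.09 and 12.47 in the KLF4 knockdown and 12.12 and 11.81 in the ZNF750 knockdown. It fell by 0.86 in the KLF4 knockdown (SE 0.19, adjusted p 0.0154), to 54.9% of control, and by 1.18 in the ZNF750 knockdown (SE 0.19, adjusted p 0.0115), to 44.2% of control. The KLF4 level of both knockdowns differed by -0.31 (SE 0.19, adjusted p 0.361), ZNF750 minus KLF4 knockdown. The dimmer KLF4 probe set was at 25.04% of control in the KLF4 knockdown (adjusted p 0.0202 over all probe sets) and at 30.3% in the ZNF750 knockdown (adjusted p 0.0542). Each targeted gene was thus lower on both arrays of its knockdown than on both control arrays, for every probe set. The fall of KLF4 in the KLF4 knockdown lost its call without control replicate 1 (-0.79, adjusted p 0.0934) and without KLF4 replicate 1 (-0.68, adjusted p 0.104), in a range of adjusted p from 0.00831 to 0.104 over the alternatives. In the ZNF750 knockdown it lost its call without control replicate 1 (-1.10, adjusted p 0.0923) and without ZNF750 replicate 2 (-1.02, adjusted p 0.0577), in a range from 0.00614 to 0.0923.

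**Figure D1:**
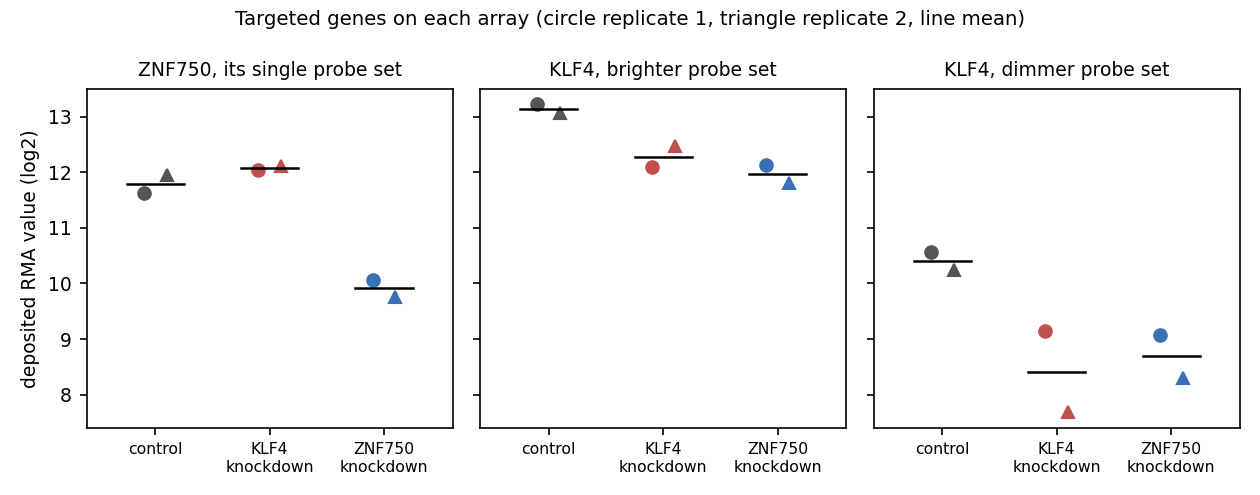
Deposited RMA values (log2) of ZNF750 and of both KLF4 probe sets on each array, with symbols for the replicates and a line at the mean of each group. KLF4 lies below both control arrays on all arrays of both knockdowns, while ZNF750 lies below them on the arrays of its own knockdown alone.

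With KLF4 knocked down, most of the measured genes of the cornified envelope fell, and most of those of the spinous layer and of the cell cycle rose. The calls of these 3 lists were lost when the correlation between genes was estimated (adjusted p = 0.633 with an estimated correlation for each). That setting called 0 of the 22 lists in each comparison, so the loss is not particular to these lists. The same KLF4 arrays stood apart from the other 4 in the signal of added poly-A control RNAs, as given below with the cell cycle genes. LCE2B and SPRR2G, which encode proteins of the cornified envelope, fell by 7.44 (SE 0.55, adjusted p 0.000361) and by 6.89 (SE 1.00, adjusted p 0.00329). KRT1, a keratin of the spinous layer, rose by 6.23 (SE 0.58, adjusted p 0.000701), and CDK1, the kinase that drives mitosis, rose by 6.41 (SE 0.38, adjusted p 0.000222). Of 19777 genes, 2649 rose and 2247 fell, 4896 in all or 24.8%, and of these 1594 rose and 1079 fell at least 2-fold. The KLF4 and control arrays did not overlap for 63.7% of genes, where chance gives 33.3%. The largest rises were those of GPR15LG (8.02), FABP7 (7.02), CXCL14 (6.88), CDK1, ANLN (6.39), TMT1A (6.31), KRT1 and ADGRG7 (6.11). The largest falls were those of KRT33B (-7.63), LCE2B, GPAT3 (-7.31), SPRR2G, MMP1 (-6.74), HMOX1 (-6.61), LCE3D (-6.52) and MMP10 (-6.45). The control means of GPR15LG, FABP7, CDK1, ANLN, TMT1A and ADGRG7 and the knockdown means of LCE2B, GPAT3 and MMP10 lay under the median of all values (5.21), that of KRT33B just above it, and the control values of LCE3D near the highest of all values. The sizes of these changes are therefore lower bounds, and their order by size is not exact. The count of changed genes was 2615 without control replicate 1, 2439 without KLF4 replicate 1 and 3084 without KLF4 replicate 2. Of the 85 named genes called in this comparison, 66 kept their call whichever array was left out. LCE3D lost its call without any 1 of the control or KLF4 arrays, with adjusted p from 0.000355 over the alternatives to 0.125 without KLF4 replicate 1.

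Of the 27 measured genes of the cornified envelope, the protein shell of the outermost cells, 0 rose and 16 fell in the KLF4 knockdown, and 18 fell when adjusted over the list alone. Their median change was -2.47, and the list was called downward (camera adjusted p 1.32e-07, but adjusted p = 0.633 with an estimated correlation). Among 30 epidermal proteases and protease inhibitors, which govern the shedding of cells, 3 rose and 17 fell, and 24 changed when adjusted over the list alone, with a median of -1.24. KLK6, a kallikrein protease, fell by 5.76 (SE 0.83, adjusted p 0.00327), and SPINK7, an inhibitor of such proteases, by 3.67 (SE 0.42, adjusted p 0.00137). The list was called downward (camera adjusted p 0.00011, but adjusted p = 0.749 with an estimated correlation). Of 21 genes of the epidermal lipid barrier, 3 rose and 7 fell, and 12 changed when adjusted over the list alone, with a median of -0.80 and camera adjusted p 0.0201 (adjusted p = 0.766 with an estimated correlation). ABCA12, a lipid transporter, fell by 1.85 (SE 0.22, adjusted p 0.00167), while ALOX15B, a lipoxygenase, rose by 3.87 (SE 0.21, adjusted p 0.000185). The lipid list lost its call without control replicate 1 (median -0.71, adjusted p 0.0575) and without KLF4 replicate 1 (-0.48, 0.232), and also with the mean of a gene's probe sets (0.0555), in a range from 0.000927 to 0.232 over the alternatives.

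The spinous layer lies below the cornified layers, and of its 25 measured genes 14 rose and 2 fell in the KLF4 knockdown, 18 when adjusted over the list alone. Their median change was 1.37 (camera adjusted p 7.87e-06, but adjusted p = 0.633 with an estimated correlation). Besides KRT1, these were led by KRT77 (5.93, SE 0.15, adjusted p 1.12e-05) and LY6D (4.69, SE 0.21, adjusted p 8.98e-05), whereas the keratin KRT80 fell by 4.47 (SE 0.68, adjusted p 0.00391). KRT10, the partner keratin of KRT1, was chosen after its values were seen and rose by 3.24 (adjusted p 0.000189). Among 14 desmosome genes, 4 rose and 3 fell, 10 when adjusted over the list alone, with a median of 0.03 (camera adjusted p 0.685). Of these, DSC1 rose by 4.11 (SE 0.30, adjusted p 0.000361). Among 19 genes of basal keratinocytes and hemidesmosomes, which anchor cells to the basement membrane, 11 rose and 3 fell, 15 when adjusted over the list alone, with a median of 0.99. That list was called upward (camera adjusted p 0.0029, but adjusted p = 0.633 with an estimated correlation), with rises of NID1 (3.67), COL7A1 (1.93) and CAV1 (1.56). KRT77 and NID1 had control means under the median of all values, so their rises are lower bounds in size. Of 26 epidermal transcription factors, 7 rose and 7 fell, 18 when adjusted over the list alone, with a median of -0.15 (camera adjusted p 0.705). PRDM1 fell by 4.22 (SE 0.48, adjusted p 0.00138), ELF3 by 3.43 (SE 0.39, adjusted p 0.00135) and SOX9 also fell (-3.02, SE 0.30, adjusted p 0.000883), while MAF rose by 3.04 (SE 0.21, adjusted p 0.000281). Of 14 stress keratins and antimicrobial proteins, 0 rose and 4 fell, 5 when adjusted over the list alone, with a median of -0.92 (camera adjusted p 0.000442, but adjusted p = 0.633 with an estimated correlation). Antimicrobial RNASE7 fell by 6.43, LCN2 by 5.83 and the calcium-binding S100P by 4.58.

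Cell cycle genes moved most as a group in the KLF4 knockdown. Of 37 measured, 32 rose and 0 fell, 33 when adjusted over the list alone, and the median change was 3.50 (camera adjusted p 6.91e-22, but adjusted p = 0.633 with an estimated correlation). With CDK1, these included TOP2A (5.93, SE 0.32), a topoisomerase, CCNB1 (5.56, SE 0.35), the mitotic cyclin, and KIF20A (5.17, SE 0.33), a mitotic kinesin. The control means of these genes, and of TRPM1 below, lay under the median of all values, so their rises are lower bounds in size. The 24 probe sets of added poly-A control RNAs moved with this group. Their mean was 7.53 ± 0.03 (SD, n = 2) in control, 7.32 ± 0.89 in the ZNF750 knockdown and 10.13 ± 0.26 in the KLF4 knockdown, and all 24 lay higher on both KLF4 arrays than on the other 4 arrays. Melanocyte markers moved with it too. Of 12 measured, 9 rose and 0 fell, 9 when adjusted over the list alone, with a median of 0.97 (camera adjusted p 3.27e-05, but adjusted p = 0.633 with an estimated correlation), among them TRPM1 (3.07), EDNRB (1.69) and OCA2 (1.16). Of 17 fibroblast markers, 5 rose and 1 fell, 6 when adjusted over the list alone, with a median of 0.02. The list was not called by camera (adjusted p 0.318) but was called upward by fry (adjusted p 0.00433). The proteoglycan DCN rose by 5.95 and COL1A1 by 2.40, each on the 1 probe set that stood for the gene. That direction, whatever the size, was shared by 5 of the 7 DCN probe sets and 4 of the 5 COL1A1 probe sets. MFAP5 fell by 1.42, which lost its call without any 1 of the control or KLF4 arrays.

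Interferon response genes split in the KLF4 knockdown, with 14 risen and 3 fallen of 34, 20 when adjusted over the list alone, and a median of 0.74 (camera adjusted p 0.000501, but adjusted p = 0.766 with an estimated correlation). IFI44 rose by 2.28 (SE 0.26) and IFI44L by 2.10 (SE 0.29), and ISG20, an exonuclease, fell by 2.59 (SE 0.37). Of 26 genes of inflammatory cytokines and NF-kB, 2 rose and 9 fell, 16 when adjusted over the list alone, with a median of -0.56 (camera adjusted p 0.000501, but adjusted p = 0.633 with an estimated correlation). IL1B fell by 3.51, the cytokine TSLP by 2.45, and TNFAIP3, an inhibitor of NF-kB, by 2.36. Of 19 genes of cholesterol biosynthesis, 9 rose and 1 fell, 13 when adjusted over the list alone, with a median of 0.53 (camera adjusted p 0.00157, but adjusted p = 0.633 with an estimated correlation), and these included the enzymes LSS (2.14) and MVD (1.60). Among 33 mesenchymal and extracellular matrix genes, 10 rose and 9 fell, 19 when adjusted over the list alone, with a median of 0.14 (camera adjusted p 0.685). LOX, which links collagens, rose by 4.48 (a lower bound, from a control mean under the median of all values) and SPARC by 4.21, while the matrix proteases MMP1 and MMP10 were among the largest falls. Of 17 p53 targets, 5 rose and 5 fell, 10 when adjusted over the list alone, with a median of 0.30 (camera adjusted p 0.958), and these included a fall of GDF15 by 3.58 and a rise of TP53I3 by 1.56. The median, mean and test differed in sign for the desmosome, mesenchymal and p53 lists.

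Genes of the unfolded protein response, which answers misfolded protein in the endoplasmic reticulum, were called downward in the KLF4 knockdown. Of 21, 2 rose and 8 fell, 12 when adjusted over the list alone, with a median of -0.61 (camera adjusted p 0.00955, but adjusted p = 0.766 with an estimated correlation). The largest falls were those of CHAC1 (-4.71), TRIB3 (-2.76) and ASNS (-4.13, against the direction of its other probe set), which are also targets of the amino acid response. The list lost its call without control replicate 2 (median -0.59, adjusted p 0.0519) and without KLF4 replicate 1 (-0.25, 0.232), in a range from 9.28e-06 to 0.232. Of 36 genes of oxidative phosphorylation, 10 rose and 1 fell, 12 when adjusted over the list alone, with a median of 0.27 (camera adjusted p 0.0019, but adjusted p = 0.766 with an estimated correlation). This call was lost without control replicate 1 (0.15, adjusted p 0.0589, in a range from 0.00014 to 0.0589). Of 32 ribosomal proteins, 0 rose and 0 fell by limma, over all genes or adjusted over the list alone, with a median of 0.10 (camera adjusted p 0.123, but 0.0481 with a mean-variance trend, the one alternative that called the list). Of 10 endothelial markers, 0 rose and 2 fell, 2 when adjusted over the list alone, with a median of -0.27 (camera adjusted p 0.0249, but adjusted p = 0.633 with an estimated correlation). That call was lost without control replicate 1 (-0.18, adjusted p 0.0561) and without KLF4 replicate 1 (-0.16, 0.107), with dim probe sets left out (0.402) and with the mean of a gene's probe sets (0.0933), in a range from 0.0134 to 0.402. Of 15 markers of Langerhans cells and leukocytes, 0 rose and 0 fell by either adjustment (camera adjusted p 0.877). Of 7 markers of simple epithelium and Merkel cells, KRT8 rose by 2.47 and KRT7 fell by 1.98, 2 when adjusted over the list alone (camera adjusted p 0.458).

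**Figure D2:**
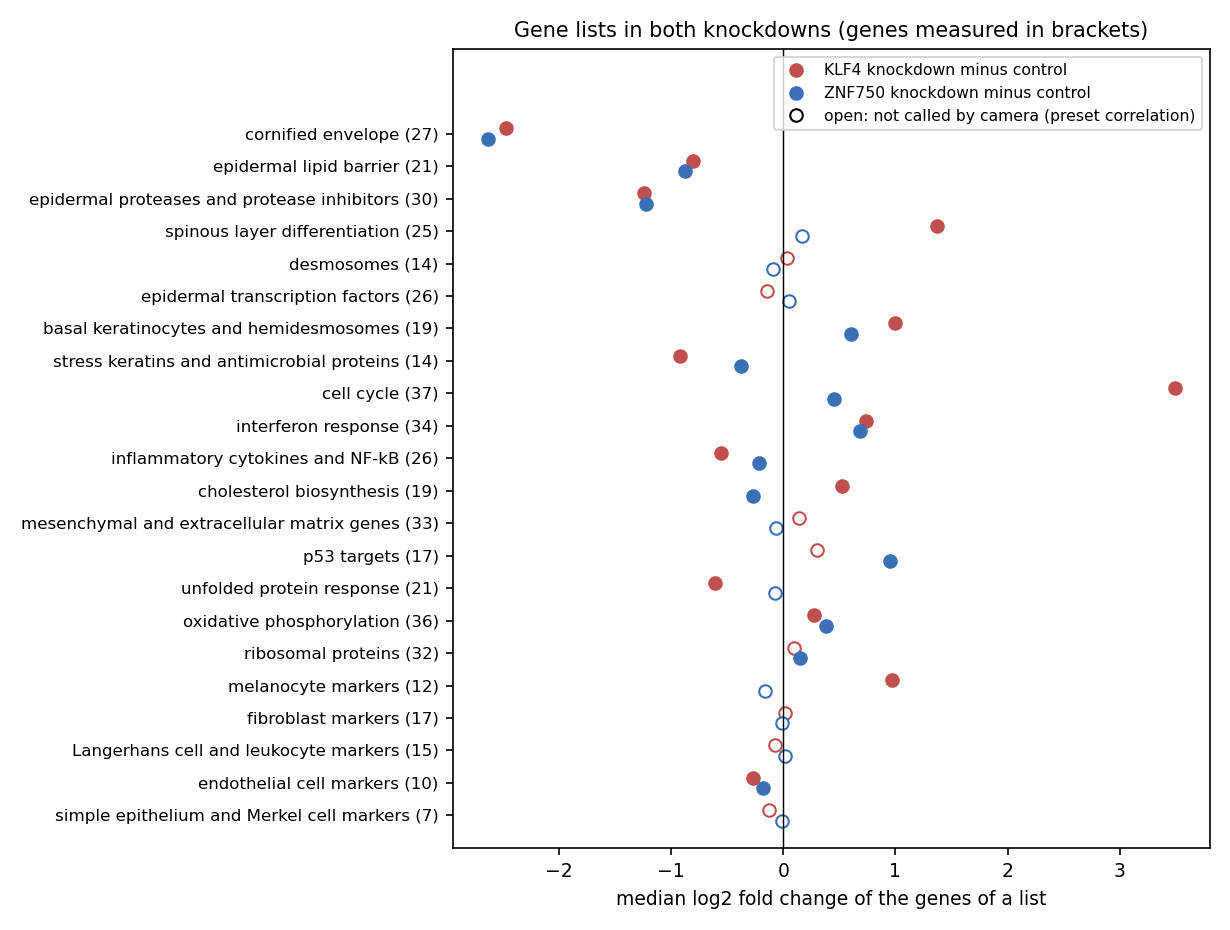
Median log2 fold change of each gene list in the KLF4 and ZNF750 knockdowns against control, with filled points for lists called by camera at the preset correlation. The cornified envelope lies at -2.47 and -2.64 in the knockdowns of KLF4 and ZNF750, and the cell cycle list at 3.50 and 0.45.

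With ZNF750 knocked down, 10 of 27 genes of the cornified envelope fell as well, and 8 of 37 cell cycle genes rose. The calls of both lists were lost when the correlation between genes was estimated (adjusted p = 0.723 with an estimated correlation for each), as were those of all other lists. LCE2B fell by 7.82 (SE 0.55, adjusted p 0.00224) and RPTN, another protein of the cornified envelope, by 4.78 (SE 0.25, adjusted p 0.00098). CCN2, a secreted matrix-associated protein, fell by 5.03 (SE 0.29, adjusted p 0.00124). CAPN14, a calpain protease, rose by 4.09 (SE 0.21, adjusted p 0.00098), and the transporter SLC16A4 by 4.06 (SE 0.16, adjusted p 0.0004). Of 19777 genes, 1880 rose and 1014 fell, 2894 in all or 14.6%, and of these 1003 rose and 577 fell at least 2-fold. The ZNF750 and control arrays did not overlap for 57.9% of genes, where chance gives 33.3%. The other large rises were those of MMP28 (3.98), APCDD1 (3.91), AKR1B10 (3.71), DAPL1 (3.58), BBOX1 (3.48) and PRR15L (3.41), and the other large falls those of PRR9 (-6.70), KRT33B (-6.50), SPRR2G (-6.03), WFDC12 (-5.95), RNASE7 (-5.82) and KCTD4 (-5.60). The control means of CAPN14 and SLC16A4 and the knockdown means of LCE2B, RPTN, CCN2 and KCTD4 lay under the median of all values, so these changes are lower bounds in size and the order by size is not exact. The count of changed genes was 332 without control replicate 1 and 803 without ZNF750 replicate 2. It was 1901 in a fit without the KLF4 arrays and also without either KLF4 replicate 1 or KLF4 replicate 2. Of the 81 named genes called in this comparison, 25 kept their call without control replicate 1. DAPL1, PRR9, KRT33B, SPRR2G, WFDC12 and RNASE7 did not, with adjusted p from 0.0624 to 0.101, where the lowest over the alternatives was 0.00087. PRR9 also lost it without ZNF750 replicate 2.

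Of the 27 genes of the cornified envelope, 0 rose and 10 fell in the ZNF750 knockdown, and 22 fell when adjusted over the list alone. The median was -2.64 (camera adjusted p 3.27e-12, but adjusted p = 0.723 with an estimated correlation), -1.30 without ZNF750 replicate 2 and -3.99 without ZNF750 replicate 1, called each time in a range of adjusted p from 1.22e-19 to 2.55e-11. FLG and IVL, classic markers of late differentiation chosen after their values were seen, differed from control by -4.00 (adjusted p 0.0559) and -2.64 (adjusted p 0.0899) and did not pass the test. The 3′ to 5′ gap of ACTB, a sign of RNA quality, was 2.43 ± 0.78 (SD, n = 2) in this knockdown, 1.49 ± 0.28 in control and 1.01 ± 0.11 in the KLF4 knockdown. Within the ZNF750 knockdown it was 1.88 on replicate 1 and 2.99 on replicate 2. Of 30 epidermal proteases and inhibitors, 1 rose and 15 fell, 20 when adjusted over the list alone, with a median of -1.23 (camera adjusted p 5.73e-11, but adjusted p = 0.723 with an estimated correlation) and of -0.74 without ZNF750 replicate 2. TMPRSS11E, a serine protease, fell by 4.71 (SE 0.36, adjusted p 0.00263), and SPINK7 by 4.16 (SE 0.42, adjusted p 0.00398). The knockdown mean of TMPRSS11E lay under the median of all values, so its fall is a lower bound in size. Of 21 lipid barrier genes, 1 rose and 4 fell, 12 when adjusted over the list alone, with a median of -0.87 (camera adjusted p 6.79e-05, but adjusted p = 0.723 with an estimated correlation) and of -0.57 without ZNF750 replicate 2. ALOX15B was the gene that rose (2.05, SE 0.21, adjusted p 0.00422). Of 14 stress keratins and antimicrobial proteins, 1 rose and 3 fell, 4 when adjusted over the list alone, with a median of -0.38 (camera adjusted p 0.0147, but adjusted p = 0.723 with an estimated correlation). That call was lost without ZNF750 replicate 2 (-0.06, adjusted p 0.333, in a range from 0.000126 to 0.333). Without ZNF750 replicate 1 the median was -0.68.

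Spinous genes went both ways in the ZNF750 knockdown, with 7 risen and 2 fallen of 25, 11 when adjusted over the list alone, a median of 0.16 and no call (camera adjusted p 0.321). DSC1 rose by 3.05 (SE 0.30, adjusted p 0.00398) and LY6D by 2.36 (SE 0.21, adjusted p 0.00331). The list was called upward without ZNF750 replicate 2 (0.18, adjusted p 0.0363, in a range from 0.0363 to 0.985). Of 14 desmosome genes, 2 rose and 2 fell, 6 when adjusted over the list alone, with a median of -0.09 (camera adjusted p 0.446). Of 19 genes of basal keratinocytes and hemidesmosomes, 8 rose and 0 fell, 10 when adjusted over the list alone, with a median of 0.61 (camera adjusted p 8.98e-05, but adjusted p = 0.723 with an estimated correlation). COL7A1, the collagen of anchoring fibrils, rose by 1.83 (SE 0.14, adjusted p 0.00263). Of 26 epidermal transcription factors, 4 rose and 5 fell, 11 when adjusted over the list alone, with a median of 0.05 (camera adjusted p 0.336). PRDM1 fell by 2.57, SOX9 by 2.22 and OVOL1 by 1.65, and these 3 lost their calls without control replicate 1 (ranges over the alternatives 0.00382 to 0.133, 0.00259 to 0.069 and 0.00443 to 0.0747). Of 37 cell cycle genes, 8 rose and 0 fell, 10 when adjusted over the list alone, with a median of 0.45 (camera adjusted p 0.000365, but adjusted p = 0.723 with an estimated correlation), 0.86 without ZNF750 replicate 1 and 0.27 without ZNF750 replicate 2. The largest of these rises were those of CDK1 (1.91) and the replication factor MCM4 (1.73), each lost without control replicate 1 (ranges over the alternatives 0.00938 to 0.0917 and 0.00614 to 0.0759), and CDK1 also without control replicate 2 and without ZNF750 replicate 2. The added poly-A control RNAs were 0.22 lower than in control in mean, at 6.69 and 7.95 on the 2 arrays.

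Among 34 interferon response genes, 9 rose and 1 fell in the ZNF750 knockdown, 16 when adjusted over the list alone, with a median of 0.69 (camera adjusted p 8.98e-05, but adjusted p = 0.723 with an estimated correlation). DDX60, a helicase, rose by 1.66 (SE 0.22, adjusted p 0.00709), and the call of the list was lost without ZNF750 replicate 1 (0.34, adjusted p 0.13, in a range from 1.08e-12 to 0.13), while the median was 1.22 without ZNF750 replicate 2. Of 26 inflammatory genes, 0 rose and 5 fell, 9 when adjusted over the list alone, with a median of -0.21 (camera adjusted p 8.98e-05, but adjusted p = 0.723 with an estimated correlation), -0.37 without ZNF750 replicate 1 and -0.12 without ZNF750 replicate 2. IL36G fell by 2.69 and IL1B by 2.21, both short of the threshold without control replicate 1 (ranges over the alternatives 0.00275 to 0.0515 and 0.00393 to 0.0512). Of 17 p53 targets, 8 rose and 0 fell, 12 when adjusted over the list alone, with a median of 0.95 (camera adjusted p 0.000365, but adjusted p = 0.723 with an estimated correlation), among them SPATA18 (1.91, SE 0.28, adjusted p 0.00957) and the DNA repair gene XPC (1.91, SE 0.21, adjusted p 0.00449). Of 19 genes of cholesterol biosynthesis, 1 rose and 4 fell, 8 when adjusted over the list alone, with a median of -0.27 (camera adjusted p 0.0106, but adjusted p = 0.723 with an estimated correlation). INSIG1 fell by 1.61 and ACAT2 by 1.26, both lost without control replicate 1 (ranges over the alternatives 0.0051 to 0.0704 and 0.00826 to 0.0814). Of 36 genes of oxidative phosphorylation, 8 rose and 0 fell, 11 when adjusted over the list alone, with a median of 0.38 (camera adjusted p 0.000144, but adjusted p = 0.723 with an estimated correlation) and of 0.24 without control replicate 1.

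Mesenchymal and extracellular matrix genes were not called as a list in the ZNF750 knockdown, with 4 risen and 8 fallen of 33, 15 when adjusted over the list alone (median -0.07, camera adjusted p 0.0826). TGFB2 fell by 2.10 (SE 0.32, adjusted p 0.0103), and the list was called downward without control replicate 2 (-0.28, adjusted p 0.00353), with dim probe sets left out (0.0285) and with centred medians (0.0499), in a range from 0.00353 to 0.33. Of 21 genes of the unfolded protein response, 0 rose and 0 fell by limma by either adjustment (median -0.07, camera adjusted p 0.675). Of 32 ribosomal proteins, 0 passed by either adjustment, but the list was called upward by a median of 0.15 (camera adjusted p 0.0142, but adjusted p = 0.741 with an estimated correlation). That call was lost without control replicate 1 (adjusted p 0.108) and without ZNF750 replicate 2 (0.084), and with dim probe sets left out (0.124), in a range from 0.000671 to 0.124. Of 12 melanocyte markers, 0 rose and 2 fell, 2 when adjusted over the list alone, with a median of -0.17 (camera adjusted p 0.0667), and the list was called downward without control replicate 2 (-0.26, adjusted p 0.018) and after a further quantile normalization (0.0328), in a range from 0.018 to 0.216. Of 17 fibroblast markers, 1 rose and 1 fell, 3 when adjusted over the list alone (median -0.01, camera adjusted p 0.966). Of 15 markers of Langerhans cells and leukocytes, CD14 rose by 3.21 (SE 0.37, adjusted p 0.00532) and 0 fell, 1 when adjusted over the list alone (camera adjusted p 0.966). Of 10 endothelial markers, 0 rose and 2 fell, 2 when adjusted over the list alone, with a median of -0.18 (camera adjusted p 0.0387, but adjusted p = 0.723 with an estimated correlation). That call was lost without control replicate 1 (adjusted p 0.0598) and without ZNF750 replicate 2 (0.0905), with dim probe sets left out (0.0981), with the mean of a gene's probe sets (0.142) and after a further quantile normalization (0.067), in a range from 0.0295 to 0.142. Without ZNF750 replicate 1 the median was -0.28. Of 7 markers of simple epithelium and Merkel cells, KRT8 (2.85) and KRT18 (0.96) rose, 2 when adjusted over the list alone (camera adjusted p 0.458), and both lost their calls without control replicate 1 (ranges over the alternatives 0.00376 to 0.0652 and 0.0375 to 0.271), KRT18 also without any 1 of the other arrays. The median, mean and test differed in sign for the transcription factor, fibroblast, Langerhans and simple epithelium lists.

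Most genes called in the ZNF750 knockdown changed the same way in the KLF4 knockdown. The genes called in both comparisons with the same sign numbered 1887, with 1117 risen and 770 fallen, and 36 were called with opposite signs. Independent lists of the same sizes would share 252 rises and 115 falls. The shared genes were 75.9% of the ZNF750 falls, 59.4% of the ZNF750 rises and 38.5% of all KLF4 calls. Among them were LCE2B, RPTN, SPRR2G, SPINK7 and KRT33B, which fell, and ALOX15B, COL7A1, LY6D and DSC1, which rose. Of the 1887, 296 differed in size between the knockdowns. The count was 257 without control replicate 1, 902 without KLF4 replicate 1, 1119 without KLF4 replicate 2 and 632 without ZNF750 replicate 2. Across all genes, which are not independent replicates, the fold changes of both knockdowns correlated at 0.703, and at 0.618 without ZNF750 replicate 2. Both rest on the same 2 control arrays, which alone gave a correlation of 0.501 in simulated unchanged groups, so part of this excess may come from the shared controls. The covariance was 0.375, against a mean of 0.0203 and a highest value of 0.0219 in 100 simulated draws, and shared calls in those draws had a median of 0 and a highest count of 1. The draws varied each gene on its own and held no deviation common to many genes of a control array.

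**Figure D3:**
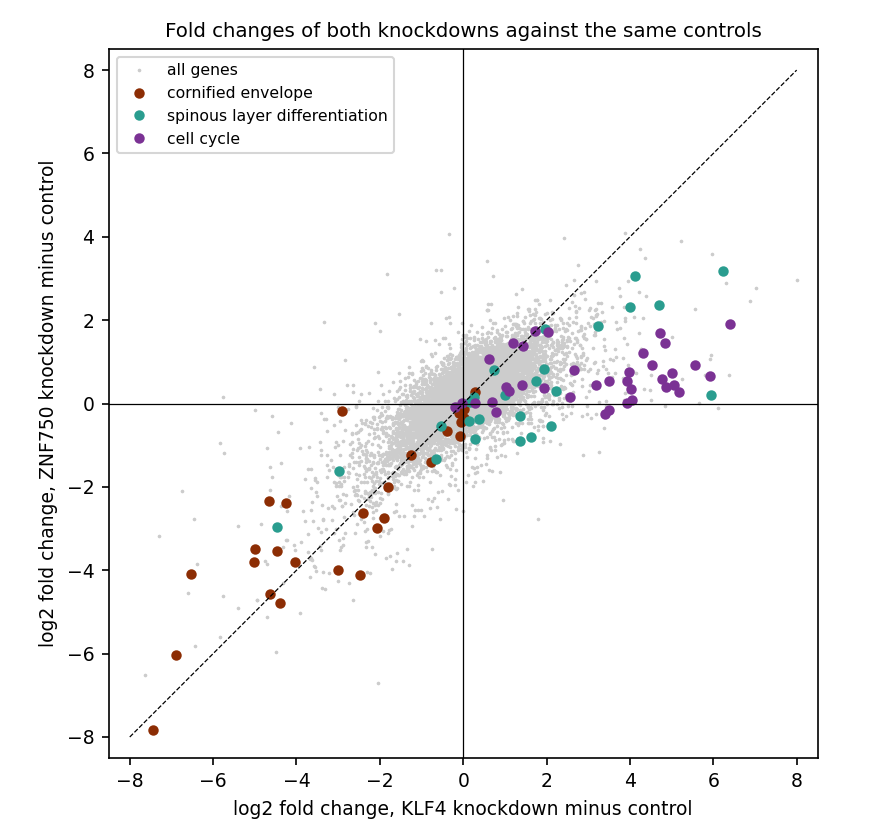
Log2 fold change of each gene in the ZNF750 knockdown (vertical) against that in the KLF4 knockdown (horizontal), both against the same control arrays, with a dashed line of equality and 3 gene lists in colour. Cornified envelope genes lie along the line at medians of -2.47 and -2.64, and cell cycle genes lie far to the right at medians of 3.50 and 0.45.

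The direct comparison of the knockdowns asks which changes were not shared. By camera at its preset correlation, the cell cycle, spinous, cholesterol, melanocyte and mesenchymal lists were called lower, and the lists of p53 targets and of the unfolded protein response higher, with ZNF750 knocked down than with KLF4 knocked down. Each of these calls was lost with an estimated correlation (adjusted p = 0.436 to 0.988), a setting that called 0 lists in any comparison. By fry, the cell cycle, spinous, cholesterol and melanocyte lists were called in the same direction (adjusted p 0.0216 each). The mesenchymal, p53 and unfolded protein response lists were not called by fry. Of 19777 genes, 1478 were higher and 1038 lower in the ZNF750 knockdown, 2516 in all or 12.7%. Of these, 602 were higher and 630 lower by at least 2-fold, so the excess of higher genes did not hold for the larger differences. The arrays of the 2 groups did not overlap for 54.7% of genes, where chance gives 33.3%. Among the largest differences upward were those of G0S2 (5.92, SE 0.37, adjusted p 0.000515), CLGN (5.30), CYP1B1 (4.94) and LCN2 (4.88), and downward those of ADGRG7 (-6.22, SE 0.15, adjusted p 1.44e-05), KRT77 (-5.73), ANLN (-5.70), DLGAP5 (-5.65) and TOP2A (-5.28). These 5 lower values in the ZNF750 knockdown, and that of CLGN in the KLF4 knockdown, lay under the median of all values, so the differences are lower bounds in size and their order is not exact. The count was 815 without KLF4 replicate 1, 769 without KLF4 replicate 2 and 1210 without ZNF750 replicate 1. Of the 74 named genes called in this comparison, 43 kept their call whichever array was left out.

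Of 37 cell cycle genes, 25 were lower and 0 higher in the ZNF750 than in the KLF4 knockdown, 27 when adjusted over the list alone, with a median difference of -3.03 (camera adjusted p 5.05e-24, but adjusted p = 0.436 with an estimated correlation). The added poly-A control RNAs were lower in the same direction, at 7.32 against 10.13. Of 12 melanocyte markers, 9 were lower and 0 higher, 12 when adjusted over the list alone, with a median of -1.03 (camera adjusted p 7.41e-11, but adjusted p = 0.436 with an estimated correlation), among them TRPM1 (-3.40) and PMEL (-2.02). Of 25 spinous genes, 12 were lower and 0 higher, 16 changed when adjusted over the list alone, with a median of -1.12 (camera adjusted p 1.36e-08, but adjusted p = 0.436 with an estimated correlation), and of -0.71 without ZNF750 replicate 2. Of 19 genes of cholesterol biosynthesis, 11 were lower and 0 higher, 13 when adjusted over the list alone, with a median of -0.76 (camera adjusted p 2.72e-09, but adjusted p = 0.436 with an estimated correlation), among them ACAT2 (-2.26), LSS (-2.14) and HMGCS1 (-1.45). Of 17 p53 targets, 5 were higher and 1 lower, 9 when adjusted over the list alone, with a median of 0.70 (camera adjusted p 0.000161, but adjusted p = 0.436 with an estimated correlation) and of 0.46 without ZNF750 replicate 2. They included GDF15 (4.46) and SESN2 (1.87), both also known as stress response genes. Of 21 genes of the unfolded protein response, 7 were higher and 0 lower, 8 when adjusted over the list alone, with a median of 0.54 (camera adjusted p 0.00616, but adjusted p = 0.988 with an estimated correlation), among them ASNS (3.66, against the direction of its other probe set), CHAC1 (3.65) and TRIB3 (2.64). That call was lost without KLF4 replicate 1 (0.13, adjusted p 0.308, in a range from 1.76e-08 to 0.308). The median was 0.92 without KLF4 replicate 2. Of 33 mesenchymal and extracellular matrix genes, 4 were higher and 10 lower, 16 when adjusted over the list alone, with a median of -0.16 (camera adjusted p 0.0393, but adjusted p = 0.831 with an estimated correlation), with LOX at -4.15 and MMP1 at 4.65. That call was lost without ZNF750 replicate 2 (-0.09, adjusted p 0.226) and with the mean of a gene's probe sets (0.0873), in a range from 0.0172 to 0.226. The median was -0.09 without KLF4 replicate 2. With an estimated correlation 0 lists were called in any of the 3 comparisons, the lowest adjusted p being 0.436, while fry called 5 lists in the KLF4 knockdown, 0 in the ZNF750 knockdown and 5 between them. Its calls in the KLF4 knockdown were spinous, basal, cell cycle, melanocyte and fibroblast genes, all upward, and between the knockdowns spinous, cell cycle, cholesterol, melanocyte and fibroblast genes, all downward.

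The cornified envelope list did not differ between the knockdowns. Of 27 genes, 1 was higher and 1 lower by either adjustment, TCHH (2.74) and FLG2 (-1.64, lost without either KLF4 array, in a range over the alternatives of 0.00803 to 0.0779), with a median of -0.15 (camera adjusted p 0.554). It was called downward without ZNF750 replicate 1 (-0.58, adjusted p 7.76e-05) and upward without ZNF750 replicate 2 (0.29, 0.013), in a range from 7.76e-05 to 0.938. The lipid barrier list, with 1 gene higher and 3 lower of 21 (4 when adjusted over the list alone, camera adjusted p 0.11), was called downward without KLF4 replicate 1 (0.00209) and without ZNF750 replicate 1 (9e-06), in a range from 9e-06 to 0.852. Proteases and inhibitors, with 1 higher and 5 lower of 30 (6 when adjusted over the list alone, camera adjusted p 0.0557), were called downward without either control array (0.0308 each), KLF4 replicate 1 (0.00921) or ZNF750 replicate 1 (7.93e-08), and with replicate number as a block (0.0336), a mean-variance trend (0.0397), the 4 arrays alone (0.0308) and centred medians (0.035), in a range from 7.93e-08 to 0.632. Within it SERPINB4 was lower by -4.43 (SE 0.31, adjusted p 0.000654). Desmosome genes, with 0 higher and 1 lower of 14 (3 when adjusted over the list alone, camera adjusted p 0.0648), were called downward without KLF4 replicate 1 (0.0165) and without ZNF750 replicate 1 (0.0111), with a mean-variance trend (0.0397) and with the mean of a gene's probe sets (0.00541), in a range from 0.00541 to 0.315. Stress keratins and antimicrobial proteins, with LCN2, S100P (4.28) and CAMP (2.41) higher of 14 (3 when adjusted over the list alone, camera adjusted p 0.0642), were called upward without KLF4 replicate 2 (0.00359) and without ZNF750 replicate 2 (0.000384), and with a mean-variance trend (0.0397), in a range from 0.000384 to 0.722.

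Epidermal transcription factors were not called between the knockdowns, with 2 higher and 3 lower of 26, 9 when adjusted over the list alone (camera adjusted p 0.646), and ELF3 (3.77) and MAF (-2.60) had the largest differences. Basal keratinocyte and hemidesmosome genes went both ways, with 6 higher and 5 lower of 19, 11 when adjusted over the list alone (camera adjusted p 0.965), such as LAMB3 (1.46). Interferon response genes, with 1 higher and 3 lower of 34 (3 when adjusted over the list alone, camera adjusted p 0.965), were called downward without ZNF750 replicate 1 (-0.20, adjusted p 0.00197) and upward without ZNF750 replicate 2 (0.49, 0.00446), in a range from 0.00197 to 0.995. Inflammatory genes, with 3 higher and 3 lower of 26 (7 when adjusted over the list alone, camera adjusted p 0.658), were called upward without ZNF750 replicate 2 (0.0318, in a range from 0.0318 to 0.821), and TSLP was higher by 2.67. Oxidative phosphorylation, with 1 higher of 36 (1 when adjusted over the list alone, camera adjusted p 0.963), and ribosomal proteins, with 0 of 32 by either adjustment (0.611), were not called. Fibroblast markers, with 1 higher and 4 lower of 17 (7 when adjusted over the list alone, camera adjusted p 0.11), were called downward without ZNF750 replicate 1 (0.0373, in a range from 0.0373 to 0.157) and by fry with all arrays (adjusted p 0.0122). Endothelial markers, with 0 of 10 by either adjustment (camera adjusted p 0.739), and those of Langerhans cells and leukocytes, with CD14 higher of 15 (3.76, 1 when adjusted over the list alone, camera adjusted p 0.965), were not called. Markers of simple epithelium and Merkel cells, with KRT7 (2.44, with 2 of its 4 probe sets in that direction) and KRT18 (1.09, lost without either KLF4 array or ZNF750 replicate 1, in a range from 0.0266 to 0.193) higher of 7 (2 when adjusted over the list alone, camera adjusted p 0.11), were called upward without KLF4 replicate 1 (0.0304) and without ZNF750 replicate 2 (0.0226), in a range from 0.0226 to 0.386. The median, mean and test differed in sign for the cornified, transcription factor, basal, interferon and oxidative phosphorylation lists.

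**Figure D4:**
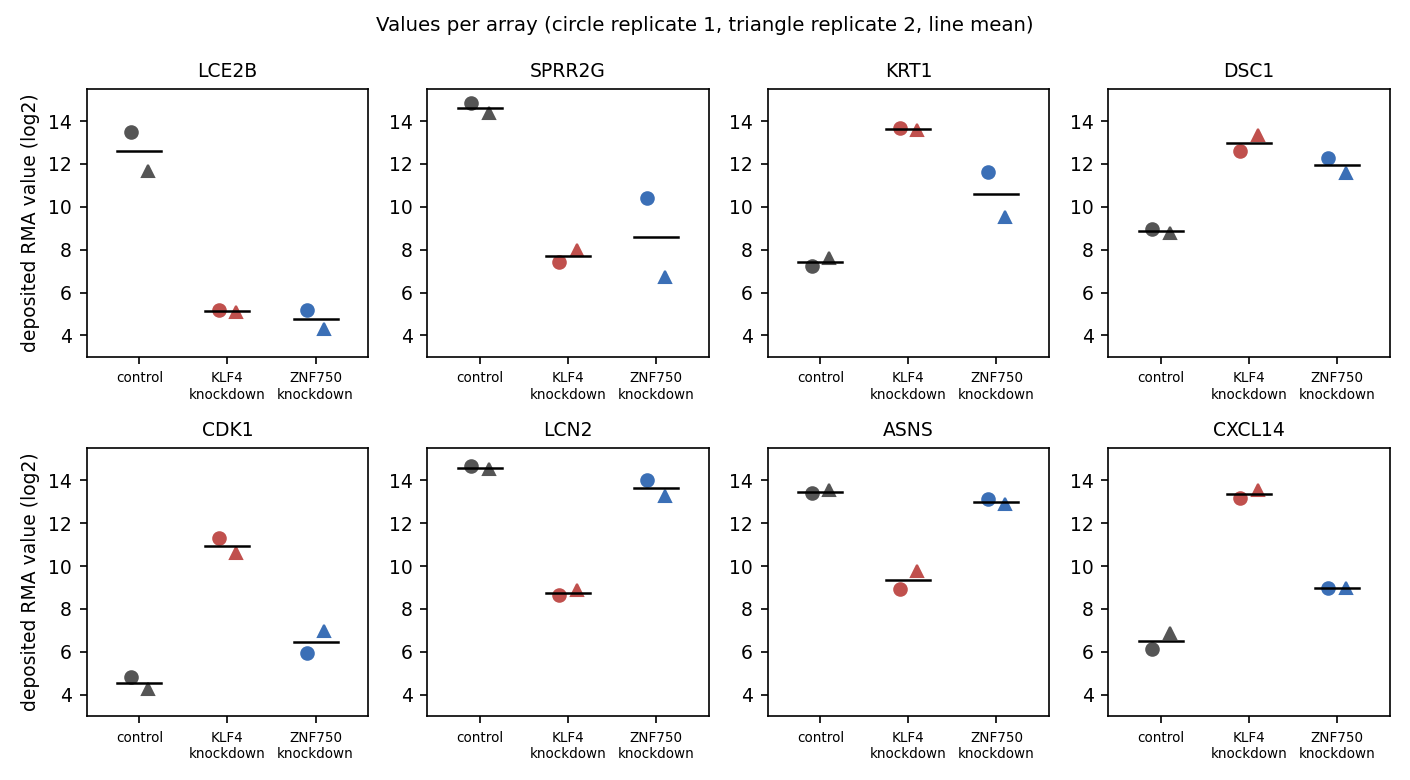
Deposited RMA values (log2) of 8 genes on each array, with symbols for the replicates and a line at the mean of each group. LCE2B and SPRR2G are low in both knockdowns, KRT1 and DSC1 are high in both, and CDK1, LCN2, ASNS and CXCL14 lie farther from control in the KLF4 than in the ZNF750 knockdown.

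Of the called named genes with several probe sets, 34 of 46 in the KLF4 knockdown, 30 of 35 in the ZNF750 knockdown and 24 of 34 between the knockdowns had all their probe sets moving in 1 direction. Among genes named above, those with a probe set in the other direction were TOP2A, TMT1A, MAF and KRT7 in the KLF4 knockdown, CDK1 and MCM4 in the ZNF750 knockdown, and TOP2A, MAF and KLF4 between the knockdowns, besides those marked. The hybridisation controls, which are added after labelling, had means of 11.23 ± 0.01 (SD, n = 2) in control, 11.32 ± 0.18 in the KLF4 knockdown and 11.18 ± 0.10 in the ZNF750 knockdown. The 3′ to 5′ gap of GAPDH was 0.33 ± 0.03 in control, 0.20 ± 0.05 in the KLF4 knockdown and 0.34 ± 0.02 in the ZNF750 knockdown.

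**Figure D5:**
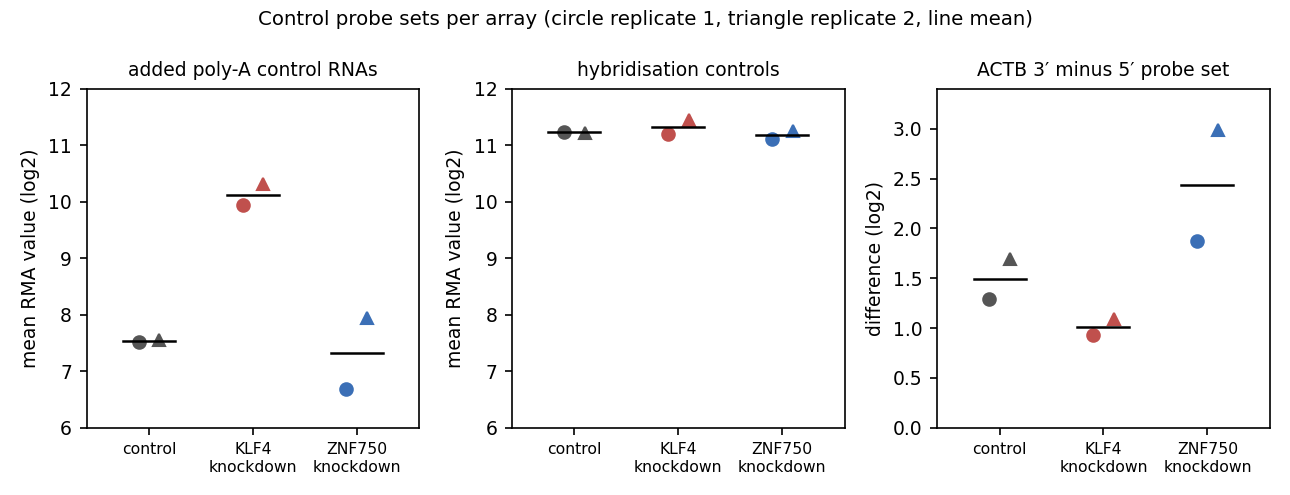
Control probe sets on each array, as the mean RMA value (log2) of the added poly-A control RNAs and of the hybridisation controls and as the log2 difference of the 3′ and 5′ probe sets of ACTB, with a line at the mean of each group. The poly-A controls lie at 9.94 and 10.31 on the KLF4 arrays and between 6.69 and 7.95 on the other 4.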

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

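The tests of handling, fibroblasts and melanocytes in this part were chosen after the results were seen. The gene groups below were singled out because their change from control differed between the knockdowns by a test of the difference itself (camera at its preset correlation, lost with an estimated one at adjusted p 0.436), and 1 measure because it came from probe sets that none of the comparisons used. The same test also called the cholesterol, mesenchymal, p53 and unfolded protein response lists, as given above, which are not taken up in this part.

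The cell cycle list changed by -3.03 (median log2) in the ZNF750 relative to the KLF4 knockdown, and cell cycle genes were far higher with KLF4 knocked down than in both other groups. By the rule set for this test, the fibroblast markers went against dividing fibroblasts. Their median change, 0.0198 with an SD of 1.66, lay below that of the cell cycle list (3.50) by more than this SD. The rule is not taken to decide, because the median level of these markers on the KLF4 arrays (5.06) is under the median of all values. In addition, fry called the list upward (adjusted p 0.00433), and DCN and COL1A1 rose. Dividing fibroblasts thus cannot be told apart from dividing keratinocytes. Dividing melanocytes cannot be told apart from dividing keratinocytes either, since melanocyte markers rose by a median of 0.97 from an already high level in control (7.31), so that their share cannot be read from it. Different handling of the KLF4 arrays cannot be told apart from the knockdown, since the added poly-A control RNAs were on average 2.70 higher on the KLF4 arrays than on the other 4, and group and handling then coincide. Loss of KLF4 itself stays open as the biological explanation and may act with any of these. KLF4 RNA was, however, at 44.2% of control in the ZNF750 knockdown and at 54.9% in the KLF4 knockdown. Its dimmer probe set was at 30.3% and 25.04%. The cell cycle list rose by a median of 0.45 in the ZNF750 and of 3.50 in the KLF4 knockdown. A like loss of KLF4 RNA thus went without a like rise. The ZNF750 knockdown also lost ZNF750, to 27.2% of control, while the KLF4 knockdown did not. These values therefore cannot tell whether the loss of KLF4 alone is the source. KLF4 protein was not measured.

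The spinous layer list differed by -1.12 (median log2) and the melanocyte markers by -1.03, both as the change in the ZNF750 knockdown minus that in the KLF4 knockdown. The added poly-A control RNAs, which lie outside the comparisons, were 2.59 (log2) higher in the KLF4 knockdown than in control, or 6.03-fold, and all 24 probe sets were higher on both KLF4 arrays than on the other 4, by 1.69 to 4.58. Different handling is thus left open in the same way for the spinous and melanocyte changes in the KLF4 knockdown. It is not excluded for the cornified fall either. A fall of like median was, however, seen in the ZNF750 knockdown (-2.64 against -2.47), where the mean of the poly-A controls was near control (7.32 against 7.53). The likeness holds for the means of 2 unlike arrays. The median was -1.30 without ZNF750 replicate 2 and -3.99 without ZNF750 replicate 1. The poly-A controls were at 6.69 on replicate 1 and 7.95 on replicate 2.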

How the results depend on the processing

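The crossed pairing in this part was chosen after seeing the data. All other alternatives were planned. Scaling shifted array medians by at most 0.04 and took the named genes called from 240 to 237 or 238, but changed 4 list calls. In the ZNF750 knockdown, a further quantile normalization called melanocyte markers (adjusted p 0.0328) and lost endothelial markers (0.067), and centring called mesenchymal genes (0.0499). Centring also called proteases between the knockdowns (0.035). The KLF4 knockdown count (4896) was 9082 over every probe set on its own, 2673 at 2-fold or more, and 2439 to 5170 with 1 array left out. The ZNF750 knockdown count (2894) was 1901 with the 4 arrays alone, 4818 over every probe set, 1580 at 2-fold or more, and 332 to 3179 with 1 array left out. The count between the knockdowns (2516) was 4478 over every probe set and 769 to 2093 with 1 array left out, and genes changed the same way in both (1887) were 257 to 2262, with their correlation (0.70) at 0.62 to 0.75. The number of tests and the stricter minimum account by construction for the counts over every probe set and at 2-fold. For the moves with arrays left out, which went both up and down, the cause was not tested. Deviations of arrays with the same number correlated at -0.24 (control and KLF4), 0.28 (control and ZNF750) and -0.33 (KLF4 and ZNF750). The numbers as given thus do not pair the arrays throughout. With the numbers of the KLF4 arrays exchanged each value would be positive, so a difference shared between replicates stays open. A replicate block gave 4426, 2453 and 2004 genes, and a crossed pairing, which exchanged the numbers of the KLF4 arrays, gave 6071, 4484 and 3674, for which the cause was not tested. KLF4 in the ZNF750 knockdown ranged from -1.33 to -1.02 with 1 array left out, and ZNF750 in the KLF4 knockdown stayed without a call in 14 of 14 alternatives (0.12 to 0.45). With an estimated correlation, whose median was 0.465 in place of 0.01, 0, 0 and 0 lists were called in place of 14, 13 and 7, and fry called 5 and 0 in the knockdowns of KLF4 and ZNF750. The cornified list, at -2.47 and -2.64, then had adjusted p 0.633 and 0.723 and by fry 0.0725 and 0.143. With 1 array left out, its median was -3.99 to -1.30 in the ZNF750 knockdown, and 8 to 13 lists were called between the knockdowns. Between the knockdowns, the cornified and interferon lists were called upward without ZNF750 replicate 2 (0.29 and 0.49) and downward without ZNF750 replicate 1 (-0.58 and -0.20), and the cause was not tested. Arrays give no depth, and differences near background (the median of all values was 5.21) cannot be read.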

Other observations

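The test of shared controls was set out before its result was seen, and the tests of transfection, RNA quality, the unfolded protein response and the amino acid response were chosen after. In the KLF4 knockdown, 27 of 36 measured amino acid response genes fell and 0 rose, 31 when adjusted over the list alone, with a median of -1.40 (camera adjusted p 1.18e-15, but adjusted p = 0.118 with an estimated correlation). This list was written after the data were seen and held no gene of the unfolded protein response list. CTH, an enzyme of cysteine synthesis, fell by 4.36, SLC7A11, the cystine transporter, by 3.41, EIF4EBP1, a repressor of translation, by 2.58, and PSAT1, an enzyme of serine synthesis, by 2.04. In the ZNF750 knockdown 1 of the 36 rose and 2 fell, with a median of -0.05, and between the knockdowns 27 were higher and 0 lower in the ZNF750 knockdown, with a median of 1.22 (camera adjusted p 1.22e-19, but adjusted p = 0.0863 with an estimated correlation).

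The fall of stress response genes in the KLF4 knockdown may be one of the whole unfolded protein response or one of the amino acid response, which the factor ATF4 drives. Within the list of 21 genes, the 15 for folding and quality control in the endoplasmic reticulum had a median of -0.31 with an SD of 0.81, against -2.30 for the other 6, the ATF4 arm. That split was made after the falls were seen and sets apart 6 of the 8 fallen genes, which by itself brings the median of the others nearer to 0, so a fall of the whole response cannot be told apart by it. The further amino acid genes fell by a median of -1.40, as a lower amino acid response through ATF4 would have it. That too stays open, since the added poly-A control RNAs set the same arrays apart. The call is also lost with an estimated correlation, a setting that called 0 of the 22 lists in each comparison.

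Genes changed the same way in both knockdowns could stem from the loss of KLF4 that both share, or from what sets both apart from control. Chance values of the shared control arrays are argued against as the whole source only where they vary independently between genes. The covariance was 0.375, and the highest of the simulated draws was 0.0219. A deviation common to many genes of the control arrays was not simulated and cannot be told apart. Poorer RNA in both knockdowns is argued against by the ACTB gap, which moved by -0.48 in the KLF4 and by 0.94 in the ZNF750 knockdown. Poorer RNA in the ZNF750 knockdown alone is not covered by this and stays open. Its ACTB gap was 1.88 and 2.99, against 1.30 and 1.69 in control and 0.93 and 1.09 in the KLF4 knockdown. The GAPDH gap was near control there (0.34 against 0.33). Transfection with siRNA, set against control cells that may not have had it, cannot be told apart from the knockdowns, since 8 of 34 interferon response genes rose in both and no group with a non-targeting siRNA is labelled. Whether the shared changes pass through KLF4 was not tested, as no array combined a ZNF750 knockdown with restored KLF4.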
